A study of Mus musculus with 10 samples.

How the data were processed

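Single-cell RNA sequencing libraries were prepared from the developing mouse skull at 5 embryonic stages, E11.5, E12.5, E13.5, E15.5 and E17.5. Control embryos carried floxed alleles of Sox4, Sox11 and Sox12, the SOXC group of transcription factors, and mutant embryos carried the same alleles together with Prx1Cre, a Cre recombinase directed at limb and cranial mesenchyme. Each stage had 1 library per genotype, 10 libraries in all, and the labels do not say how many embryos entered a library. Per the labels' protocols, tissue was digested with LiberaseTM and libraries were made with the 10x Genomics 3' kit, version 2 at E15.5 and version 3 at the other stages. At E17.5 the dermis and hypodermis were removed before digestion. The source label was cranium at E11.5 and E12.5 and calvarium at the later stages. The tissue label differed within the pairs at E15.5 and E17.5, where it was mesenchyme for the control and bone for the mutant library. The submitters' note also says that titles and characteristics of 4 samples, the control libraries of E15.5 and E17.5 and the mutant libraries of E13.5 and E15.5, were corrected after deposit. The labels as they now stand were used.

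For each library the authors deposited a matrix of UMI counts, which are whole numbers of distinct molecules per gene and cell barcode, not normalized. Per the submitters' processing notes these were made with Cell Ranger on mouse build mm10, and Seurat version 3 was used afterwards. Per the file headers the Cell Ranger version was 6.0.0 at E11.5 and E12.5, 3.0.0 at E13.5 and 3.0.2 at E17.5, while the version at E15.5 is not given in the sources used here. The matrices held 32285 genes at E11.5 and E12.5, 31053 at E13.5 and E17.5 and 27998 at E15.5. Genes were matched by Ensembl identifier, and the 26940 genes in every matrix held from 99.4% to 99.8% of a library's UMIs. The authors also deposited tables of their own comparisons at E11.5, E12.5 and E13.5, with a fold change and a p-value per gene. The headers of these deposited tables give no base for the log fold change. It was read as a natural log, since the median ratio of the deposited genotype values to the mesenchymal log2 ratios computed here was 0.974 on that reading and 0.675 when read as log2, with the natural log nearer to 1 at each of the 3 stages. The sign of the deposited genotype values is control over mutant, whereas every ratio computed here is mutant over control. Gene positions are from GENCODE M21 on build GRCm38, the same assembly as mm10.

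Cells with at least 500 detected genes and at most 10% mitochondrial counts were kept, which left 7289 to 16940 cells per library. Scrublet, as provided in scanpy, was run per library. Its automatic threshold marked under 0.5% of cells in 8 of the 10 libraries, so the 5% of cells with the highest doublet score were left out of each library. The remaining cells of a stage, both libraries together, were scaled to 10000 counts per cell, log transformed and reduced to 2000 variable genes and 30 principal components. They were clustered with the Leiden method at resolution 1 on 15 nearest neighbours. No batch correction was applied. Clusters were named from markers of 19 cell classes. A cluster was mesenchymal-like when at least 8 of 12 mesenchymal markers lay at least 1 log2 unit above the median of neural, endothelial, immune and erythroid clusters, with a mean of at least 1.4. Other classes needed at least 3 markers (4 for classes with at least 8 markers) raised by at least 1 log2 unit and a mean marker difference of at least 0.7. Osteoblast-, chondrocyte-, dermal fibroblast-, meninges- and tendon-like subclasses of mesenchyme needed 3 such markers and a mean of at least 1. Clusters led by Ttr or Tph1, genes of choroid plexus and pineal gland, stayed unnamed. Names rebuilt in this way can differ from those of the study.

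UMI counts were summed per library over the mesenchymal-like cells and tested with edgeR's quasi-likelihood test, with stage as a factor, TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. Because each stage has 1 library per genotype, no stage was tested alone. The 5 stages served as the replicates of a genotype difference shared across development, so the error is the variation of that difference between stages, and differences confined to some stages count as error. The libraries of a stage are paired by design, and their deviations from the genotype means correlated by 0.701 to 0.919. The same test was applied to endothelial-like and immune-like cells, which lie outside the lineage at which Prx1Cre is directed and numbered at least 153 per library. A model with an interaction of genotype and embryonic day asked for a trend of the difference with age. Gene lists, 31 in all, were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. They covered contractile, osteoblast, osteoprogenitor and suture, chondrocyte, dermal fibroblast, meninges and tendon genes, S phase and G2/M genes and reported SOXC targets. Others covered Wnt, BMP, TGF-beta, hedgehog, FGF, YAP/TEAD, retinoic acid, p53, dissociation stress, glycolysis and hypoxia, fibrillar matrix and sex-linked genes. The last group held markers of endothelial, mural, immune, erythroid, keratinocyte, muscle, Schwann, neuronal and neural progenitor cells. The contractile list was written knowing that the study describes myofibroblast-like progenitors, so it is not independent of these samples. Within a stage, a list was described by its median log2 ratio of (CPM + 1), set among 10000 random lists of the same size drawn from genes within 50 ranks of mean expression. Class shares were compared across stages by an exact two-sided sign-flip permutation test of the log odds.

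Tests, alternatives, gene lists, markers and the rule for named genes were fixed before the data were examined. The rule took up to 10 genes each way at an adjusted p under 0.05, at a mean of at least 10 CPM and changed the same way at all 5 stages, or where none passed the 5 with the smallest p each way. It also took up to 4 members per list by p, and per stage the 5 genes with the largest ratio each way at 50 CPM or more in a library. For the trend it took the 5 genes each way with the smallest p at an adjusted p under 0.05. Floxed and sex-linked genes were always named. Ribosomal, mitochondrial, haemoglobin, predicted and unnamed genes were counted and not named by this rule. The thresholds for naming clusters, the share of cells left out as doublets and 3 kinds of alternative were chosen after the data were examined. These 3 were equal numbers of cells from both libraries in each cluster, clusters with at least 95% of cells from 1 library left out, and the stages whose libraries differ in sex left out. The other alternatives were DESeq2, RLE scaling, no low-count filter, no stage block, leaving out each stage in turn, doublets kept, and a filter of 1000 genes and 5% mitochondrial counts. Leiden resolution 2, all kept cells, osteoblast-, chondrocyte- and tendon-like clusters left out, equal cell numbers per stage and the 3 youngest stages alone were also run.

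On counts simulated at the observed means and library sizes of mesenchyme, edgeR recovered 32.8% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 81.8% of those changed 4-fold, and 10.3% of its calls were false. With equal cells per cluster the recovered shares were 59.7%, 79.1% and 97.0% with 8.2% false calls. For endothelial cells they were 38.8%, 73.1% and 95.5% with 11.0% false calls, and for immune cells 29.9%, 61.2% and 95.5% with 9.5%. For the trend they were 70.1%, 80.6% and 97.0% with 5.2%. There each fold was a change of the genotype ratio per embryonic day, a larger change over the stages, so these shares do not compare with the others. The share of false calls thus lay above the nominal 5% in each of these edgeR simulations. With DESeq2 it was 21.4% for mesenchyme, 14.1% for the trend and 5.7% with equal cells per cluster. For endothelial and immune cells DESeq2 gave 7.3% and 3.7%. A list of 20 genes raised 1.5-fold was called by camera, and 0 of 20 unchanged lists were called. Genes were drawn independently in this simulation, so it could not show false list calls that arise when members of a list vary together. Intervals of CPM are exact Poisson intervals and those of shares exact binomial (Clopper-Pearson) intervals at 95%, and both cover counting error only, not differences between embryos. The work used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, igraph 0.11.9, scipy 1.17.1 and scikit-learn 1.9.0.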

Results

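The series profiled single cells of the mouse head at 5 stages of skull formation, from loose mesenchyme at E11.5 to ossifying calvaria at E17.5. It compared control embryos with floxed Sox4, Sox11 and Sox12 and mutant embryos that also carried Prx1Cre, which addresses what the SOXC proteins do in cranial mesenchyme. SOXC proteins are HMG-box transcription factors active in embryonic progenitors. Each genotype had 5 libraries, 1 per stage. At E11.5 the control library held 14590 barcodes and 59502646 UMIs and the mutant library 16532 barcodes and 56779232. The E12.5 pair held 17335 barcodes with 60757145 UMIs in the control and 14158 with 50563543 in the mutant. At E13.5 the control library had 11036 barcodes and 76933246 UMIs and the library labelled mutant 13072 and 84070204. The E15.5 libraries had 9779 (control) and 10484 (mutant) barcodes, with 47837821 and 50727755 UMIs. At E17.5 the control had 13765 barcodes and 76551365 UMIs and the mutant 15030 and 55902412. Median UMIs per barcode ran from 2756 in the E11.5 mutant to 5386 in the E13.5 control library, and at E17.5 they were 5224 in the control and 3469 in the mutant. Mesenchymal-like cells numbered 2200 control and 2833 mutant at E11.5, 5519 and 3596 at E12.5, 8008 and 6854 at E13.5, 4144 and 6058 at E15.5, and 7328 and 7587 at E17.5. Their summed UMIs ranged from 13453223 in the E11.5 control to 57440961 in the E13.5 control.

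Floxed transcripts were lower in the mesenchyme of the mutant library for Sox4 and Sox12 at all 5 stages and for Sox11 at 4 of 5, and none was lost completely. Sox4 went from 496 CPM in control to 308 in mutant at E11.5, from 505 to 315 at E12.5, from 421 to 351 at E13.5, from 148.5 to 103 at E15.5 and from 173 to 74 at E17.5. Those mutant levels were 62.1%, 62.3%, 83.3%, 69.3% and 42.9% of control. Sox12 stood at 47.9%, 61.8%, 79.5%, 38.2% and 25.7% of control in the same order, from a control level of 61.6 CPM at E11.5 and 14.4 at E17.5. Sox11 stood at 70.3% at E11.5, 83.6% at E12.5, 51.2% at E15.5 and 38.4% at E17.5. At E13.5, Sox11 went against the label, with 257 CPM in the library labelled mutant and 187 in the control, a ratio of 1.38 (exact counting interval 1.34 to 1.42). That library is therefore called the library labelled mutant, and each direction given for E13.5, or for a fit that includes it, takes its label as it stands. Sox4 (chromosome 13, 28948919 to 28953713, minus strand), Sox11 (chromosome 12, 27334264 to 27342574, minus) and Sox12 (chromosome 2, 152393611 to 152398063, minus) are positioned on GRCm38. Because the labels do not say which part of each gene is deleted, 3' tags outside that part can remain after deletion and these levels do not measure recombination. Across the 5 stages edgeR gave Sox4 a log2 fold change of -0.63 (SE 0.12, Benjamini-Hochberg adjusted p 0.117), Sox12 -1.01 (SE 0.20, 0.117) and Sox11 -0.47 (SE 0.22, 0.388), so none passed over all genes, while DESeq2 gave adjusted p values of 0.00023, 0.000138 and 0.216 in that order. Over all kept cells rather than mesenchyme, the edgeR log2 fold change of Sox11 was 0.25.

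**Figure D1:**
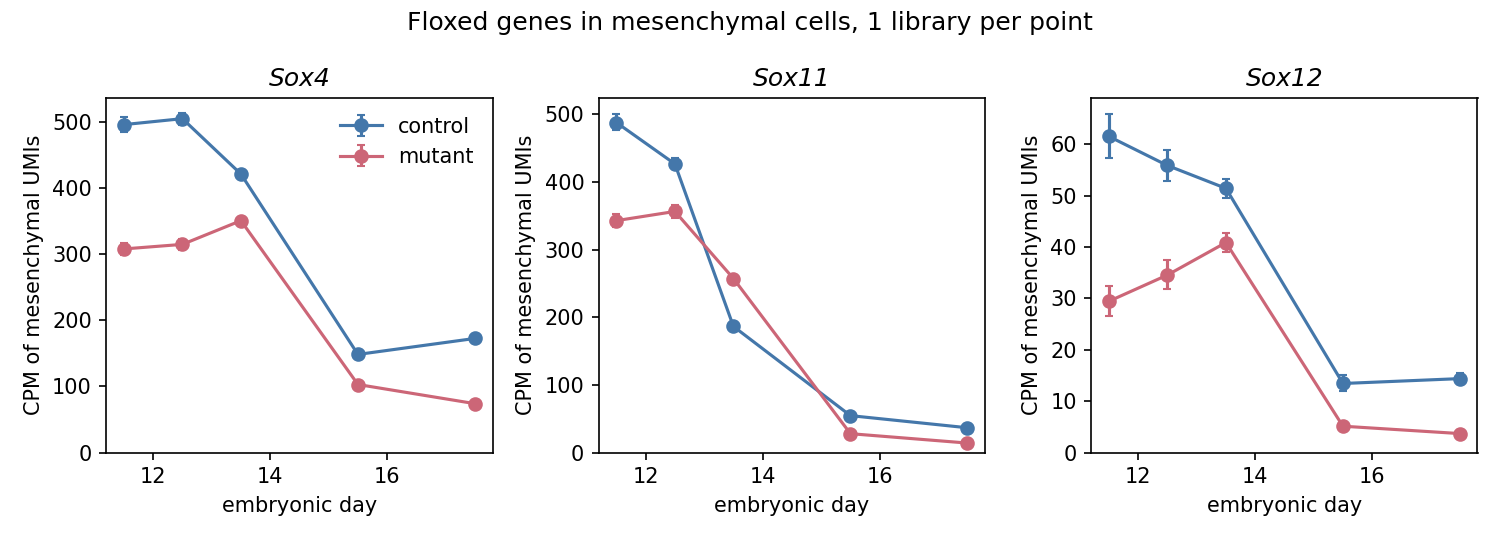
CPM of Sox4, Sox11 and Sox12 summed over mesenchymal-like cells against embryonic day, 1 library per point, control and mutant, with exact Poisson bars for counting error. Mutant points lie under control at each stage except Sox11 at E13.5, where 257 CPM in the library labelled mutant stands over 187 in the control.

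Outside the mesenchyme, Sox4 and Sox11 in endothelial-like cells and Sox4 in immune-like cells were also lower in most mutant libraries. In endothelial-like cells, Sox4 stood at 74.6%, 56.4%, 65.6%, 98.0% and 58.7% of control from E11.5 to E17.5, and Sox11 at 94.5%, 66.2%, 43.7%, 98.5% and 61.2%. Sox4 in immune-like cells was 78.1%, 42.1%, 95.8%, 107% and 89.9% of control. Sex differed within 2 pairs. At E12.5 the control library held 49.4 CPM of the Y-linked Ddx3y and 0 counts of Xist, the RNA of the inactive X, while the mutant held 848 CPM of Xist and 0 counts of Ddx3y. At E13.5 it was the control that held Xist (1136 CPM, with 0 counts of Ddx3y), and the library labelled mutant held Ddx3y at 70.2 CPM. Eif2s3y, Kdm5d and Uty followed Ddx3y, with at most 2 counts in the E12.5 mutant and 0 in the E13.5 control. At the remaining stages both libraries held Y-linked transcripts, with Ddx3y from 30.1 to 69 CPM, and the E17.5 mutant also held 1.48 CPM of Xist. A count of 0 allows up to 0.124 CPM in the E12.5 control mesenchyme and 0.184 in the mutant (3 counts).

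In mutant mesenchyme, 6 genes rose and 2 fell across the 5 stages out of 15542 tested. S100a6, an EF-hand calcium-binding protein, rose most among genes at 10 CPM or more, from a mean of 263 to 538 CPM (log2 fold change 1.19, SE 0.10, n = 5 libraries per genotype). Uba7, the enzyme that activates the ubiquitin-like protein ISG15, rose from 14.7 to 29.9 CPM, Khk, ketohexokinase of fructose metabolism, from 11.3 to 20.7, and Txnip, a thioredoxin-binding protein, from 55.6 to 83.2. Pold4, a small subunit of DNA polymerase delta, rose from 40.1 to 62.5 CPM. Nradd, a death-domain membrane protein related to the p75 neurotrophin receptor, fell from 58.7 to 32 CPM (log2 fold change -0.88, SE 0.06). Each of these 6 genes moved the same way at 5 of 5 stages, and edgeR's Benjamini-Hochberg adjusted p was 0.0254 for S100a6, Uba7 and Khk, 0.0298 for Txnip, 0.0439 for Pold4 and 0.0214 for Nradd. The log2 fold changes (SE) were 1.07 (0.09) for Uba7, 0.99 (0.09) for Khk, 0.69 (0.07) for Pold4 and 0.68 (0.07) for Txnip. S100a6 was 1.32, 1.37, 1.28, 0.58 and 1.16 log2 units higher at the successive stages. The remaining calls, named after their values were seen because their means lay under 10 CPM, were Ihh, the hedgehog ligand of hypertrophic cartilage (1.3 to 4.49 CPM, log2 1.86, SE 0.18), and Adamts7, a metalloprotease (12.9 to 6.87 CPM, log2 -0.91, SE 0.09), each at an edgeR adjusted p of 0.0298 and 5 of 5 stages. Some of these genes also lead clusters that the libraries filled unequally: S100a6 was among the leading genes of E13.5 meninges-like clusters, and Ihh of an E17.5 chondrocyte-like cluster with 19 control and 137 mutant cells.

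**Figure D2:**
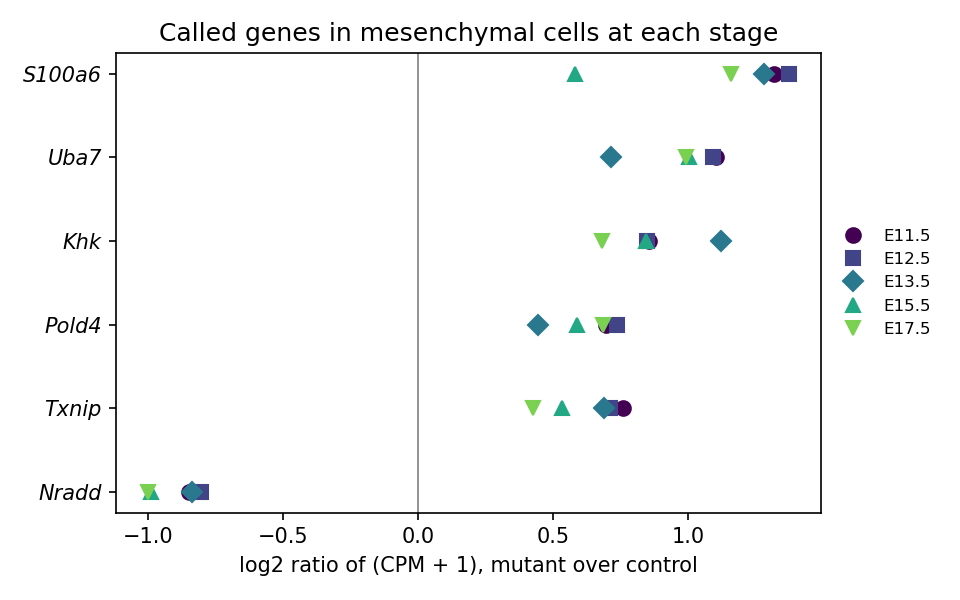
Log2 ratio of (CPM + 1), mutant over control, in mesenchymal-like cells at each embryonic day for S100a6, Uba7, Khk, Pold4, Txnip and Nradd, 1 pair of libraries per point. S100a6 lies between 0.58 and 1.37 and Nradd is under 0 at each of the 5 stages.

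On GRCm38 the 6 genes lie at chromosome 3, 90612882 to 90624181 (S100a6), chromosome 9, 107975505 to 107984060 (Uba7), chromosome 5, 30921431 to 30931248 (Khk), chromosome 19, 4231899 to 4233634 (Pold4), chromosome 3, 96557957 to 96561883 (Txnip), all on the plus strand, and chromosome 9, 110621135 to 110624452, on the minus strand (Nradd). The test found 2265 genes at an unadjusted p under 0.05, and DESeq2 called 512 genes, 330 higher and 182 lower, including all 8. The count depended on the stages included: edgeR called 22 genes without E13.5 (6 of the 8 among them), 1 without E15.5 and 0 without E11.5, E12.5 or E17.5, where 1685, 1671 and 1683 genes had an unadjusted p under 0.05. It was also 0 without the pairs of differing sex (1999 at an unadjusted p under 0.05), over all kept cells (1434), with the 3 youngest stages alone (1367) and without the stage block (119).

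Mesenchymal clusters were filled unequally by the libraries of a stage, so the comparison was repeated, after the data were seen, with equal numbers of control and mutant cells from each cluster. This balances the clusters but not cell states within a cluster. Where a library held more cells of a cluster, cells were taken in a single random draw, and variation between draws was not assessed. With equal cells per cluster, 214 genes rose and 166 fell out of 14414, 7 of the earlier 8 among them. Of the 380, 285 stood at 10 CPM or more, moved alike at 5 of 5 stages and were of the kinds of gene that the naming rule allows. Among those 285 genes the strongest risers were Ndufa4l2, a mitochondrial protein and mural cell marker that leads mural-like clusters at E11.5, E12.5 and E13.5 (112 to 260 CPM, log2 2.14, SE 0.42), the glycoprotein hormone subunit Gpha2 (12.8 to 35.4 CPM, 1.31, SE 0.14) and the keratan sulfate proteoglycan Kera (6.46 to 14.6 CPM, 1.3, SE 0.19). They were followed by the interferon-inducible Ifi27l2a (log2 1.22, SE 0.17), the dipeptidase Dpep1 (1.2, SE 0.14), S100a6 (1.06, SE 0.08), the matrix protein Abi3bp (1.02, SE 0.16), the thromboxane receptor Tbxa2r (1, SE 0.09), Tmem88, a membrane protein that binds Dishevelled (0.96, SE 0.11), and the metallothionein Mt1 (30.4 to 56.1 CPM, 0.94, SE 0.09). Floxed Sox12 itself led the genes that fell (39.9 to 22.4 CPM, log2 -0.90, SE 0.12), and Sox4 also fell (-0.65). Next came Plppr3, a phospholipid phosphatase-related protein of neurons (-0.89, SE 0.08), Ctxn1 (67.1 to 37.4 CPM, -0.84, SE 0.08), the focal adhesion proteins Fblim1 (-0.84, SE 0.12) and Tes (45.1 to 25.2 CPM, -0.84, SE 0.09), and Aplp1, a homologue of the amyloid precursor protein (-0.83, SE 0.08). The last were Kcnmb4, a potassium channel subunit (-0.83, SE 0.14), the PR-domain factor Prdm6 (-0.80, SE 0.08), Tmem132a (-0.77, SE 0.10) and the glutamine transporter Slc38a1 (-0.73, SE 0.12). All 20 named genes moved the same way at 5 of 5 stages, and their edgeR adjusted p lay between 0.00358 (S100a6, Tbxa2r, Plppr3, Ctxn1 and Aplp1) and 0.039 (Ndufa4l2). Sox11 did not pass (-0.38, edgeR adjusted p 0.285), at 79.4%, 98.6%, 107%, 58% and 38.9% of control.

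Fixed lists held further genes that passed with equal cells per cluster. Matrix genes Mfap4 (456 to 623 CPM, log2 0.52), Col3a1 (1806 to 2339 CPM, 0.44), Lox (0.53) and Fbn1 (0.26) rose, as did Ifitm5 of osteoblasts (0.75), Thbs4 of tendon (1.03), Egln3 of the hypoxia response (0.82), the suture gene Tfap2b (0.59), the Wnt effector Tcf7 (0.43) and Cxcl12 (0.28). Genes that fell were Stmn1, a microtubule-destabilising protein (1111 to 749 CPM, -0.45), Tead2 (-0.54) and Ezh2 (-0.25), all on the list of reported SOXC targets, and Foxd1 (-0.50), with edgeR adjusted p of 0.0272, 0.0125, 0.0309 and 0.0203. The list of reported SOXC targets as a whole did not pass here (adjusted p 0.0946, 4 of 7 negative). The fall of Stmn1 was not confined to mesenchyme at E12.5. Its log2 ratio there was -0.85 in mesenchyme with equal cells per cluster and -0.97 in endothelial-like cells. It was -1.25 in immune-like, -1.99 in erythroid-like and -0.69 in neural cells. By camera, 13 of the 31 lists were higher and 1 lower. Fibrillar matrix was strongest (adjusted p 4.33e-08, 0.299 with an estimated correlation, 4 members called over all genes and 11 adjusted over the list alone). Glycolysis and hypoxia followed (8.61e-06, 0.505 with an estimated correlation, 1 member and 11 adjusted over the list alone). Marker lists of other cells made up 6 of the 13, endothelial markers next after glycolysis (0.000222, median 0.59), then mural (0.00131), immune (0.0146), Schwann cell and neuronal (0.0178 each) and erythroid markers (0.0387). Dermal fibroblast (0.000731, 0.286 with an estimated correlation), tendon (0.0013), TGF-beta response (0.0178), osteoblast (0.0435) and dissociation stress genes (0.0438) were also higher, and the list that was lower was S phase (0.0032, 0.505 with an estimated correlation). None held with an estimated correlation, and fry called dermal fibroblast genes alone (adjusted p 0.0278). The number of genes was 133 without E13.5, 173 without E15.5, 402 without E17.5, 63 without E11.5 and 49 without E12.5. It was 0 without the pairs of differing sex (1638 at an unadjusted p under 0.05) and without the stage block (68), against 524 by DESeq2 with all pairs.

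Over all mesenchymal cells, camera placed 10 of the 31 lists higher and 3 lower in the mutant, but 0 held with an estimated correlation, 0 passed by fry (smallest adjusted p 0.239) and 0 list members passed over all genes. List calls given with a stage left out use the preset correlation. Tendon, dermal fibroblast, fibrillar matrix and meninges genes were among the higher lists. The tendon list had 6 of 7 members with a positive log2 fold change (median 0.48, camera adjusted p 0.00145, 0.497 with an estimated correlation), led by Thbs4 (log2 1.38, SE 0.29) and Kera (1.26, SE 0.32), with 2 members passing adjusted over the list alone. Dermal fibroblast genes had 14 of 18 positive (median 0.35, adjusted p 0.000906, 0.509 with an estimated correlation, 4 passing adjusted over the list alone), among them Ly6a (20 to 42.2 CPM) and Dcn, a collagen-binding proteoglycan (913 to 1140 CPM). Fibrillar matrix had 18 of 20 positive (median 0.34, adjusted p 1.46e-05, 0.509 with an estimated correlation, 3 over the list alone), with Mfap4 at 479 and 671 CPM, Col3a1 at 1893 and 2426 and the cross-linking enzyme Lox at 168 and 231. Meninges genes had 10 of 12 positive (median 0.51, adjusted p 0.000618, 0.509 with an estimated correlation, 4 over the list alone), such as the chemokine Cxcl12 (214 and 297 CPM), the GABA transporter Slc6a13 (7.75 and 19) and the claudin Cldn11 (52.6 and 90.0). With equal cells per cluster the meninges list lost its call (median 0.02, adjusted p 0.981), and meninges-like cells were a larger part of mesenchyme in the mutant libraries where they were found. Dermal fibroblast-like cells were 0.3002% of control and 8.25% of mutant mesenchyme at E17.5, the stage at which the dermal list had its highest median (0.725). At E17.5 dermis and hypodermis were removed before digestion and the tissue label differed within the pair, so dissection can set this share.

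Skeletal lists were less uniform. Chondrocyte genes had 14 of 17 positive (median 0.35, camera adjusted p 0.0113, 0.744 with an estimated correlation, 1 passing adjusted over the list alone), led by Comp, a cartilage matrix protein (43.2 to 61.1 CPM, log2 0.81, SE 0.17), but the list turned downward without the E13.5 pair (adjusted p 0.76) and lost its call with equal cells per cluster (8 of 17 positive, adjusted p 0.981). At E13.5 the chondrocyte-like share of mesenchyme was 1.02% in the control and 18.6% in the library labelled mutant. Osteoblast genes had 11 of 20 positive (median 0.06, adjusted p 0.106, 0 over the list alone), with Ibsp at log2 1.51 (SE 0.48) and Ifitm5 at 1.3 (SE 0.33), and that list passed without E17.5 (8.49e-08), without E11.5 (0.0436) and with equal cells per cluster (0.0435, but 0.645 with an estimated correlation and 0.356 by fry). The osteoprogenitor and suture list had 13 of 20 positive (median 0.08, adjusted p 0.204). Its member Tfap2b, a neural crest transcription factor, passed adjusted over the list alone (46.6 to 72.7 CPM, log2 0.74, SE 0.16, higher at 5 of 5 stages), while Alx1 stood at 62.6 and 98.8 CPM. Contractile genes of myofibroblasts showed no common direction: 5 of 17 were positive, the median was -0.09 and camera's direction down, but the mean was 0.05 (adjusted p 0.703, 0 over the list alone). That list, which is not independent of these samples, was higher without the E13.5 pair (adjusted p 0.0489).

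Proliferation genes made up most of the lower side. S phase genes were negative in 25 of 27 (median -0.20, camera adjusted p 1.09e-05, 0.721 with an estimated correlation, 0 over the list alone), with the ribonucleotide reductase subunit Rrm2 at 87.6 and 65.9 CPM. G2/M genes were negative in 30 of 31 (median -0.20, adjusted p 4.32e-05, 0.744 with an estimated correlation, 0 over the list alone), including the spindle genes Tacc3 (log2 -0.30) and Aurka (-0.39), and lost their call without E15.5 (0.128). With equal cells per cluster the G2/M list turned upward and did not pass (17 of 31 positive, adjusted p 0.752), and it also turned upward with the 3 youngest stages alone (0.0649). Reported SOXC targets were negative in 5 of 7 (median -0.14, adjusted p 0.0113, 0.509 with an estimated correlation), and Stmn1 (1220 to 723 CPM, log2 -0.75, SE 0.12), Tead2, a DNA-binding partner of YAP (120 to 76.8 CPM, -0.66, SE 0.11) and Ezh2, the histone H3K27 methyltransferase (134 to 108 CPM, -0.33, SE 0.10) were the 3 that passed adjusted over the list alone. That list lost its call without E17.5 (0.0646) or E12.5 (0.0789) and with equal cells per cluster (0.0946).

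Among signalling lists, TGF-beta response genes were positive in 9 of 10 (median 0.29, camera adjusted p 0.00521, 0.509 with an estimated correlation, 0 over the list alone), with Postn at log2 0.79 (SE 0.25) and Ccn2 at 0.60, and this call was lost without E15.5 (0.0748). Glycolysis and hypoxia genes were positive in 16 of 18 (median 0.20, adjusted p 0.000473, 0.509 with an estimated correlation, 3 over the list alone), including the prolyl hydroxylase Egln3 (0.79, SE 0.15), Pfkp (0.61), Pdk1 (0.37) and Vegfa (0.35). No common direction passed for Wnt (8 of 16 positive, median -0.05, adjusted p 0.64), BMP (5 of 13, -0.12, 0.703), hedgehog (5 of 6, 0.08, 0.669), FGF (6 of 10, 0.06, 0.987) or YAP/TEAD genes (6 of 12 measured, -0.03, 0.499, 1 over the list alone). FGF passed without E15.5 (0.0367) and YAP/TEAD without E12.5 (0.0281). Retinoic acid genes had 8 of 10 positive (median 0.26, adjusted p 0.204), with the retinol receptor Stra6 at log2 0.98, and passed without E11.5 (0.00874). Neither p53 genes (5 of 14 positive, median -0.14, adjusted p 0.531), dissociation stress genes (10 of 17, 0.02, 0.877) nor the sex-linked list (4 of 5, 0.20, 0.825) passed, though stress genes did with equal cells per cluster (0.0438, but 0.505 with an estimated correlation). The Wnt, BMP, hedgehog, FGF, retinoic acid, p53, stress and sex-linked lists each had 0 members passing adjusted over the list alone.

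Markers of other cell types moved in the same mesenchymal sums. Mural markers were positive in 8 of 9 (median 0.52, camera adjusted p 0.000113, 0.497 with an estimated correlation, 3 over the list alone), with Ndufa4l2 at 106 and 247 CPM and Vtn at 79.7 and 146. Endothelial markers were positive in 10 of 10 (median 0.48, adjusted p 0.00117, 0.509 with an estimated correlation, 2 over the list alone), such as Cdh5 (0.68) and Egfl7 (0.51), and lost the call without E13.5 (0.0621). Schwann cell markers were positive in 8 of 8 (median 0.74, adjusted p 0.0409, 0.509 with an estimated correlation, 0 over the list alone), and did not pass without E13.5 (0.104) or E17.5 (0.284). Muscle markers were positive in 13 of 13 (median 1.65, adjusted p 0.106), passing without E15.5 (1.75e-07) and without E11.5 (0.00672). Immune markers (7 of 9 positive, 0.18, 0.493) passed without E12.5 (0.0017), erythroid markers (3 of 10, -0.26, 0.372) without E11.5 (2.33e-06) and keratinocyte markers (3 of 10, -0.35, 0.494) without E17.5 (0.000886). Neuronal markers (7 of 10, 0.21, 0.204) passed without E12.5 (0.0253), and neural progenitor markers (8 of 10, 0.36, 0.204) without E11.5 (0.045) or E12.5 (0.00749). None of these last 6 lists had a member passing adjusted over the list alone. With equal cells per cluster immune (0.0146), erythroid (0.0387, on the higher side) and neuronal markers (0.0178) passed, but not with an estimated correlation (0.587, 0.784 and 0.299). In that fit 1 erythroid and 1 neural progenitor marker passed adjusted over the list alone.

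Single stages, each with 1 library per genotype and therefore no test, differed in kind. At E11.5 the mutant library held more Emp3 (96.3 to 315 CPM, ratio interval 3.07 to 3.48 from counting error), Dcn (79.2 to 248), Crip1 (127 to 345), Fmo1 (23.8 to 60.9) and S100a6 (166 to 414). It held less Tes (66.8 to 28.8), the ephrin Efna4 (58.4 to 27.9), Sox12, Cd24a (203 to 102) and the growth factor Mdk (1626 to 832). At E12.5 S100a6 (157 to 408 CPM), Ccdc80 (54.9 to 141), the stress-response gene Nupr1 (23.9 to 61.9), the interferon-induced Ifitm3 (29.7 to 72.5) and Dcn (199 to 477) were highest over control. Pcsk1n (68.6 to 12.6), the histone gene Hist1h2ap (278 to 63.2), the neuronal genes Rtn1 (189 to 57.6) and Stmn3 (116 to 38.6), and the chemokine Cxcl14 (135 to 44.4) were lowest. Hist1h2ap was lower in each of the 6 cell classes compared at E12.5, as were the imprinted Nnat (1083 to 511 CPM) and predicted genes Gm10260 (247 to 1.78) and Gm10076 (1349 to 476). At E11.5 the ribosomal protein gene Rpl29 was higher (185 to 1127 CPM) and BC004004 lower (198 to 39.6) in each of 6 classes. The rise of Rpl29 was not confined to E11.5. Its log2 ratios at E12.5 and E13.5 were 0.90 and 1.25 in mesenchyme and 0.85 and 0.98 in endothelial-like cells. They were 0.86 and 1.08 in immune-like and 0.08 and 0.74 in erythroid-like cells.

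Smooth muscle genes stood out at E13.5. Acta2, smooth muscle actin, was at 1567 CPM in the control and 400.2 in the library labelled mutant (ratio 0.256, counting interval 0.251 to 0.259), and Tagln (602 to 204 CPM), Actg2 (91.3 to 28.9), Cxcl14 (551 to 166) and Veph1 (131 to 41.2) were also lower. The difference was not confined to mesenchyme: Acta2 and Tagln had log2 ratios of -1.86 and -1.89 in endothelial-like, -2.19 and -2.09 in immune-like and -3.52 and -3.31 in erythroid-like cells of that pair. Genes highest in the library labelled mutant were Vtn (57.4 to 264), Wwp2 (20.1 to 91.8), Sparcl1 (32.4 to 137), the IGF-binding Igfbp5 (64.1 to 265) and the cartilage gene Otor (24.4 to 92.8). Clusters led by Acta2 and Tagln held 751 and 613 control against 293 and 148 cells labelled mutant. At E15.5 bone genes were higher in the mutant library, with Ibsp, bone sialoprotein, at 486 and 1734 CPM, Ifitm5 at 67.1 and 203 and Smpd3 at 16.1 and 53.2, beside Ifi27l2a (14.2 to 71.8) and Tac1 (28.8 to 103). Osteoblast-like cells were also a larger part of that library, 3.58% of mesenchyme against 1.33% in the control (217 and 55 cells). Irx1 (124 to 20.7), Mgst1 (108 to 21.3), Lmcd1 (73 to 14.7), Twist2, a regulator of dermis and osteoblasts (509 to 110.0), and Stmn2 (128 to 29.7) were lowest. Ibsp and Mgp (503 to 1433 CPM) were higher in each of the 5 cell classes compared at E15.5, and the keratinocyte genes Krt14 (81.1 to 18.7), Krt1 (136 to 35.5), Krt10 (198 to 69.7), Krt15 (89.4 to 21.3) and Lgals7 (204 to 63.3) were lower in each. At E17.5 the osteocalcin genes Bglap (234 to 39.4 CPM) and Bglap2 (135 to 26.7), which are near-identical copies, Spp1, osteopontin (1851 to 803), Sox4 and Mgst3 (70.8 to 32.1) were lower in the mutant, where osteoblast-like cells made up 4.15% of mesenchyme against 5.54% in the control. Those highest in it were the muscle genes Acta1 (2.14 to 225 CPM), Tnnc2 (1.02 to 109), Myl1 (1.41 to 117) and Ttn (0.577 to 66.2), and Ttr of choroid plexus (0.986 to 118). All 5 were higher in each of the 4 classes compared, and skeletal muscle-like cells made up 0.0346% of the control and 4.62% of the mutant library at that stage.

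**Figure D3:**
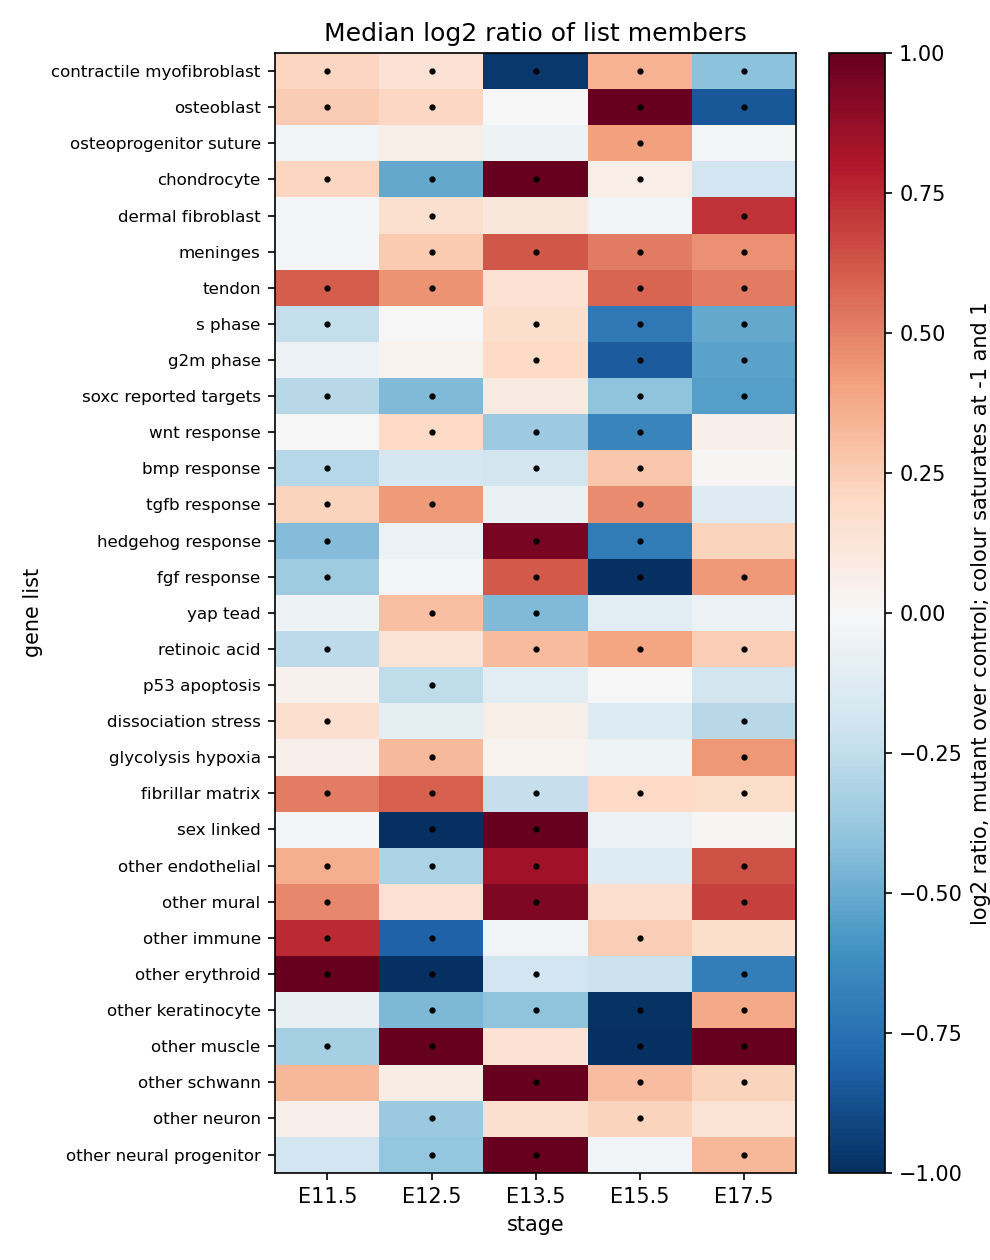
Median log2 ratio of (CPM + 1), mutant over control, for each gene list (vertical) at each embryonic day (horizontal) in mesenchymal-like cells, with colour saturating at -1 and 1 and black dots where the median lies outside the central 95% of 10000 random lists. Contractile genes are at -0.97 at E13.5, and osteoblast genes go from 1.04 at E15.5 to -0.85 at E17.5.

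List medians within a stage lay outside the central 95% of matched random lists in 99 of 155 cases, against 7.8 expected from the percentiles alone, but members of a real list vary together and random lists do not, so such an excess can arise between any 2 libraries. Osteoblast genes had medians of 0.25, 0.21, -0.01, 1.04 and -0.85 from E11.5 to E17.5. Contractile genes stood at 0.22, 0.14, -0.97, 0.35 and -0.41, and chondrocyte genes at 0.22, -0.51, 1.1, 0.07 and -0.19. Proliferation genes were lower at the late stages, with G2/M medians of -0.84 at E15.5 and -0.53 at E17.5 and S phase medians of -0.71 and -0.51, while at E13.5 they were 0.20 and 0.17. Tendon genes were positive at all 5 stages (0.61, 0.45, 0.15, 0.59 and 0.52), and reported SOXC targets negative at 4 (-0.28, -0.44, 0.09, -0.40 and -0.55). Hedgehog genes stood at 0.95 and FGF genes at 0.61 at E13.5, against -0.70 and -1.09 at E15.5. Marker lists of other cells had medians as large: muscle -2.02 at E15.5 and 2.37 at E17.5, neural progenitor 1.23 at E13.5, keratinocyte -0.99 at E15.5, and erythroid 1.24 at E11.5 and -1.71 at E12.5. Of the 50 gene entries named at single stages, 49 kept their direction under each of 8 alternatives.

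No gene passed the test for a genotype difference that moved steadily with age. The interaction of genotype and embryonic day gave 0 genes by edgeR at an adjusted p under 0.05, with 630 at an unadjusted p under 0.05, and 13 by DESeq2. Stra6, named after its value was seen, came closest, gaining 0.58 log2 units per day (SE 0.04, edgeR adjusted p 0.0951).

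In endothelial-like cells, outside the lineage at which Prx1Cre is directed, 0 of 10988 genes passed by edgeR (1008 at an unadjusted p under 0.05), and DESeq2 called 26. The smallest p values on the higher side belonged to Wfdc1 (2.16 to 15.3 CPM, log2 3.04, SE 0.39), Igfbp3, an IGF-binding protein (273 to 458 CPM, 0.80, SE 0.11), Fxyd5 (159 to 262 CPM), Klhl5 (18 to 32.6 CPM) and the early response gene Ier3 (0.76, SE 0.12). On the lower side were Lyve1, the hyaluronan receptor of lymphatic vessels (36.6 to 7.23 CPM, log2 -2.01, SE 0.35), Khdrbs3 (40.9 to 19.4 CPM), Klhl4 (54.1 to 31.1), Ppp1r14b (503 to 363) and Hmgb3 (281 to 207). Their edgeR adjusted p lay between 0.051 and 0.106, and each except Ier3 (4 of 5) had the same sign at 5 of 5 stages. An E15.5 cluster with the lymphatic genes Prox1, Mmrn1 and Ccl21a held 67 control and 4 mutant cells. Without E15.5, 10 endothelial genes passed, without E11.5 3, without E12.5 or E13.5 1, and without E17.5 0.

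Immune-like cells gave 0 of 11172 genes by edgeR (461 at an unadjusted p under 0.05) and 3 by DESeq2. Apoe, the lipid carrier of macrophages (5758 to 9150 CPM, log2 0.62, SE 0.08), and the iron carrier Trf (219 to 325 CPM, 0.58, SE 0.08) had the smallest adjusted p, 0.201 and 0.21 by edgeR. The chemokine Ccl12 (0.54, SE 0.10), the complement receptor C5ar1 (0.59, SE 0.13) and Runx1 (90.2 to 134 CPM) followed, all positive at 5 of 5 stages. On the lower side, the neutrophil gene Stfa1 (244 to 127 CPM, -1.18, SE 0.26) was joined by Fam220a (-0.82) and by the keratinocyte genes Krt14 (-1.59, SE 0.34), Krt1 (-1.39, SE 0.32) and Sbsn (-1.29), each at an edgeR adjusted p of 0.985. Keratinocyte-like cells were also fewer in the E15.5 mutant library. Without E11.5 or E12.5 3 immune genes passed, without E15.5 1, and 23 without the pairs of differing sex.

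Cell class shares differed between the libraries of a stage, but 0 of the 17 classes with at least 1% of cells in some library moved one way at all 5 stages. A class found in neither library of a stage counted as no difference there, so many classes could not have done so. Meninges-like cells were higher in the mutant at 3 stages and lower at 0, and tendon-like and dermal fibroblast-like cells higher at 2 and lower at 0. Mural-like cells and mesenchyme outside the named subclasses had the smallest exact two-sided permutation p, 0.125 (n = 5 stages), each with 4 of 5 stages one way. That other mesenchyme was a lower share of mutant mesenchyme (mean log odds -0.732, SD 0.715). At E11.5 it was all of the mesenchyme in both libraries. Its difference at that stage comes only from the 0.5 cells added to each count for the log odds. Without E11.5 the share was lower at 4 of 4 stages (mean log odds -0.979). Mural-like cells stood at 0.659% of control and 1.26% of mutant cells at E11.5, 0.721% and 1.70% at E12.5, 1.71% and 4.39% at E13.5 and 1.81% and 3.50% at E17.5, but 3.11% and 1.99% at E15.5 (mean log odds 0.541, SD 0.573). Without E15.5 they were higher at all remaining stages, as were endothelial-like cells. Endothelial-like cells made up 1.92% of the control (exact binomial interval 1.65% to 2.22%) and 5.50% (5.06% to 5.96%) of the library labelled mutant at E13.5, and 6.63% and 4.81% at E15.5 (mean log odds 0.239, exact p 0.4375). Immune-like cells (mean log odds 0.133, exact p 0.6875) and erythroid-like cells (exact p 0.625) had no common direction. Neurons were 24% and 22.5% at E11.5, 11% and 19.8% at E12.5, and at later stages mainly in mutant libraries, with 0.0109% and 3.95% at E13.5 and 0.0289% and 4.11% at E15.5 (exact p 0.25). Chondrocyte-like cells were 14.6% of control and 23.3% of mutant mesenchyme at E12.5, 1.02% and 18.6% at E13.5, 2.44% and 1.55% at E15.5 and 16.3% and 17.8% at E17.5 (mean log odds 0.663, exact p 0.375). Without E13.5 that mean was 0.056, and at Leiden resolution 2 the share was higher at 1 stage and lower at 3. Meninges-like cells were 10.3% and 22.6% of mesenchyme at E13.5, 0.724% and 1.42% at E15.5 and 0.505% and 13% at E17.5 (mean log odds 0.994, exact p 0.25, 0.401 without E17.5). That class depends on cluster names: an E15.5 cluster with Cldn11, Gjb6 and Slc16a9 (341 control and 1009 mutant cells) was not named meninges-like, nor was an E17.5 cluster of mostly control cells that shares Slc16a9 and Cxcl12 with the meninges-like cluster of that stage. The smallest p that 5 stages allow is 0.0625, and dissection, which differed in label at E15.5 and E17.5, can set such shares. Thresholds chosen after the data were seen kept out of the osteoblast-like class an E15.5 cluster with Alpl, Sp7, Dlx5 and Spp1 (381 control and 850 mutant cells). They also left unnamed haemoglobin-led clusters at E15.5 (37 and 103, 35 and 11 cells) and E17.5 (147 and 69).

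Some clusters came mostly from 1 library, which leaves open whether they are cell types. Of the mesenchyme, those with at least 95% of cells from 1 library were an E12.5 cluster led by Notch2 and Slc39a1 (2772 control and 19 mutant cells), an E13.5 chondrocyte-like cluster led by Matn4 and Matn1 (1 control cell and 569 labelled mutant) and at E17.5 a meninges-like cluster led by Slc16a9 and Fxyd5 (37 and 984) and a dermal fibroblast-like cluster led by Clec3b and Mfap5 (20 and 593). Nearly as one-sided at E17.5 were clusters led by Cpxm1 and Ltbp2 (956 and 52), Basp1 and Atp1b1 (578 and 36) and Sfrp2 and Gpha2 (114 and 1486), and a dividing dermal fibroblast-like cluster (2 and 33). Unnamed E12.5 clusters held 3885 control and 87 mutant cells, and 627 and 1, and an unnamed E17.5 cluster with the muscle genes Mylpf, Myl1 and Acta1 held 7 and 377.

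Control mesenchyme held more transcripts of bone matrix at the later stages, where stage is confounded with kit version, gene annotation and dissection, and each value is 1 library. Col1a1, the main collagen of bone, went from 380 CPM at E11.5 to 1103, 5133, 6212 and 16140 at the following stages, and Ibsp from 0.149 at E11.5 to 486 at E15.5 and 1340 at E17.5. In mutant libraries Col1a1 stood at 894, 1995, 4374, 11780 and 14690 CPM. Col2a1, the cartilage collagen, lay between 201 and 319 CPM in controls until E15.5 and reached 4551 at E17.5, and Dcn went from 79.2 at E11.5 to 2364 at E15.5 and 1229 at E17.5. Acta2 peaked in the E13.5 control at 1567 CPM, from 63.6 at E11.5 and 287 at E12.5, and stood at 75 at E15.5 and 209 at E17.5, whereas the mutant libraries held 126, 296, 400.2, 100.5 and 152. Tropomyosin Tpm1 had its highest control level at the same stage (1923 CPM), as did the osteoprogenitor factor Twist1 (923). The homeobox gene Msx1 went from 350 to 71.2 CPM and the retinoid-binding Crabp1 from 1153 to 15.1 between E11.5 and E17.5. The chromatin protein Hmgb2, high in dividing cells, went from 1359 to 274 CPM and the thymidylate synthase gene Tyms from 148 to 60.2.

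The authors' deposited tables of genotype differences at E11.5, E12.5 and E13.5 come from the same libraries, so a match checks reading and direction and is not independent evidence. Of 805 of the listed genes found here, 795 (98.8%) had the same direction in the mesenchymal sums as in the authors' deposited tables, or 701 of 708 (99%) without ribosomal protein, predicted and sex-linked genes. The authors' deposited table for E13.5 gave log ratios of unstated base, control over mutant, of 2.079 for Acta2, 1.706 for Cxcl14 and 1.627 for Tagln, where the log2 ratios of mutant over control here were -1.97, -1.73 and -1.56. These 3 lie nearer to the values here if read as log2, while over 378 genes of that stage the median ratio of deposited to present values was 1.058 read as natural log and 0.733 read as log2. In the authors' deposited table Igfbp5 was at -1.631 and Sox11 at -0.517 at E13.5, both on the side higher in the library labelled mutant, where the values here were 2.03 and 0.46. At E12.5 the authors' deposited table listed Sox4 at 0.326 and Stmn1 at 0.771, both lower in the mutant, and here their log2 ratios were -0.68 and -1.14. At E11.5 the authors' deposited table had S100a6 at -0.985 and Rpl29 at -2.17, against log2 ratios of 1.32 and 2.60 here. Genes that the authors' deposited E11.5 table listed as lower also stood lower in 78.2% of cases in endothelial-like, 54.5% in immune-like and 92.7% in erythroid-like cells. These shares were 97.8%, 92.2% and 96.7% for the E12.5 table and 65.6%, 69.1% and 94.9% for the E13.5 table. For genes listed as higher they were 67.9%, 85.7% and 87.5% at E11.5, 88%, 72% and 30% at E12.5 and 66.5%, 87.6% and 28.1% at E13.5.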

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

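The tests of unequal cluster shares, of sex and of exchanged labels were chosen only after the results they bear on were seen. Values far from the others of their group were looked for in 100 groups of 5 libraries or stages with Dixon's test, which marked 14, where chance alone marks about 1 in 20.

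The library labelled mutant of E13.5 was the deepest, at 84070204 UMIs where the other mutant libraries held 50563543 to 56779232. S100a6 was 0.579 log2 units higher in mutant mesenchyme at E15.5, against 1.158 to 1.373 at the other stages, and Uba7 0.7123 at E13.5 against 0.9906 to 1.1. Osteoprogenitor and suture genes had a median log2 ratio of 0.409 at E15.5 (other stages -0.053 to 0.06), dermal fibroblast genes 0.725 at E17.5 (-0.024 to 0.161) and Schwann cell markers 1.15 at E13.5 (0.071 to 0.333).

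The E15.5 control library stood apart in several classes, with 4.693% keratinocyte-like cells (other controls 0% to 0.9375%), 3.668% mast cell-like (0% to 0.4688%) and 1.545% skeletal muscle-like cells (0% to 0.03457%), and 5.985% of its mesenchyme dermal fibroblast-like (0% to 0.3002%). Osteoblast-like cells made up 5.54% of the E17.5 control mesenchyme (0% to 1.327% in the other controls), and meninges-like cells 10.3% of the E13.5 control mesenchyme (0% to 0.7239%). Among mutant libraries, E15.5 held 8.639% immune-like cells (3.027% to 4.355% elsewhere) and E17.5 4.615% skeletal muscle-like cells (0% to 0.01218%).

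Sox11 in mesenchyme stood at 138% of control in the library labelled mutant at E13.5 and under control at the other 4 stages, and this difference between stages was not tested. RNA of the neural cells that were found almost only in that library was weighed first: neural markers account for a median of 24.9% of the Sox11 excess of 70.8 CPM (7.73% to 29.7% over 5 markers), which argues against it as the whole source. Unequal cluster shares were also tested, and with equal cells per cluster the ratio was 1.07 (1.03 to 1.12), so they may carry most of the excess. Whether they carry all of it cannot be told, since this interval covers counting error only and the cells came from a single random draw. Neural RNA and cluster shares were each weighed alone. Together they could account for the whole excess over control, and this was not tested. An exchange of labels between the libraries of the pair is argued against: of 133 genes called without this pair with equal cells per cluster, 91% (84.8% to 95.3%) went the called way here as labelled, and Sox4 and Sox12 stood at 83.3% and 79.5% of control. That interval is binomial over genes, which vary together within 1 pair of libraries, so it does not cover differences between embryos. It is therefore not settled that any Sox11 excess is left to explain. For what may be left, a sample of another origin, transcripts left after deletion and a true difference in Sox11 at this stage remain open and were not tested.

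Acta2, Cxcl14, Veph1, Actg2 and Tagln were the genes lowest over control in the library labelled mutant at E13.5. Ratios of these 5 genes as a set, here and for E12.5 below, were taken without the 1 CPM added elsewhere. With equal cells per cluster their median log2 ratio was -0.89 against -1.67 over all mesenchymal cells, so 53.4% was left and unequal cluster shares are not the whole account. The sexes of the pair differ, and at E12.5 they differ the other way round. There the 5 genes had a median log2 ratio of 0.05 with a highest value of 0.39. That lies under what a sex difference alike at both stages would give on its own. A sex difference offset at E12.5 by a genotype difference could give the same values, so sex as a part of the account stays open. Acta2 was also lower in endothelial-like (-1.86), immune-like (-2.19) and erythroid-like cells (-3.52) of the pair, so RNA free in the droplets and a difference of the whole library stay open and were not tested. Also open are the dissection of the samples and a stage-specific effect of the SOXC genes, each resting on 1 pair of libraries that may not recur.

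More genes were called when both libraries gave equal cells to each cluster (380 genes) than over all mesenchyme (8). Unequal cluster shares are a candidate explanation for the smaller count, since the median SD of the log2 ratio over stages was 0.181 with equal cells per cluster and 0.225 with equal cells per stage, lower by 19.8%. Mesenchymal RNA free in droplets is argued against as the reason why the 380 genes also move elsewhere: 134 of them that endothelial cells hold at least as highly still had 46.8% of the mesenchymal change there (39.4% to 61.3%). The reverse, RNA of other cells counted in the mesenchymal sums, was not tested and stays open. Endothelial, mural, immune, Schwann cell, neuronal and erythroid marker lists were higher in this fit at the preset correlation. A difference that all classes of a library share cannot be told apart from an effect of the genotype, since the called genes had 56.0% of their mesenchymal change in endothelial cells (47.6% to 65.5%) and 51.6% in immune cells (42.1% to 58%), 87.2% and 86.6% with the same sign, and the interval spans the bound set for it. These intervals, and the one given for free RNA, come from resampling genes. The genes share the same libraries and vary together, so the intervals do not cover differences between embryos or pairs. The 16 assignments of control and mutant within stages, the real one included, are too few for a share under 0.05. Only the real one reached 380, and 6 was the highest count of the others.

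The same limit of 16 assignments, the real one included, holds for the other counts. For mesenchyme the real count was 8, and the highest of the others was 1. For gene lists the real count was 13, and 11 of the 16, the real one included, gave as many or more, up to 20. The trend had a real count of 0 against at most 2 in the others. Endothelial cells had 0 against at most 6 and immune cells 0 against at most 4. A real count of 0 is matched by all 16, since no count lies under 0, so these comparisons cannot tell. The 24 splits that part fewer stage pairs had a median of 0 genes in endothelial and in immune cells. Their highest counts, 52 endothelial and 180 immune genes, came from splits that part 1 pair and so rest on control against mutant at a single stage.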

How the results depend on the processing

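Equal cells per cluster, leaving out clusters of 1 library and leaving out the pairs of differing sex were chosen after the results were seen. Of the 6 genes named as changed in mesenchyme, 61 of 114 alternative fits kept the call and 53 kept the direction only, and no direction turned. The number of genes changed in mesenchyme was 512 with DESeq2, 24 without a low-count filter, 18 with doublets kept, 65 without osteoblast-, chondrocyte- and tendon-like clusters and 380 with equal cells per cluster. It was 0 without the replicate block, over all kept cells, with the 3 youngest stages and without the pairs of differing sex, and 0 to 22 leaving out each stage. RLE scaling, Leiden resolution 2, the stricter cell filter, equal cells per stage and leaving out clusters of 1 library moved it by at most 1.5 times, though the stricter filter shared only 4 of the 8 calls and leaving out clusters of 1 library 6. With equal cells per cluster the count was 653 without a filter, 0 without the replicate block, 201 with the youngest stages, 0 without the pairs of differing sex and 49 to 402 leaving out each stage. For the trend it was 13 with DESeq2, 1 without a filter and 2 with equal cells per cluster.

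Endothelial counts were 26 with DESeq2, 268 without a filter, 1 with doublets kept, 1 without the pairs of differing sex and 0 to 10 leaving out each stage. Immune counts were 3, 28 and 23 with DESeq2, without a filter and without those pairs, and 0 to 3 leaving out each stage. Gene lists called numbered 0 with an estimated correlation, 0 by fry and 8 without the replicate block. The chondrocyte list turned downward without the osteoblast-, chondrocyte- and tendon-like clusters (adjusted p 0.881), which removes its own cells, and its adjusted p ran from 0.000125 to 0.76 leaving out each stage, turning downward without E13.5. G2/M genes turned upward with the youngest stages alone (0.0649) and with equal cells per cluster (0.752). Sox4 (-0.63) and Sox12 (-1.02), 2 floxed genes, passed with DESeq2, and with equal cells per cluster the same 2 passed (-0.65 and -0.90), while Sox11 was 0.25 over all kept cells. Classes moving one way at each stage were 0 to 2 leaving out each stage. Matches with the deposited tables were 91.3% with equal cells per cluster. Beyond the clusters removed, the cause was not tested. The smallest endothelial library held 153 cells, and 10988 genes could be tested there against 15542 in mesenchyme.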

Other observations

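No test in this part was chosen after its result was seen, and the values below describe single pairs of libraries. Fibrillar matrix genes had median log2 ratios of 0.51, 0.60, -0.23, 0.20 and 0.19 from E11.5 to E17.5, so the E13.5 pair went against the other 4, the same stage at which contractile genes stood at -0.97. Meninges genes stood at -0.02, 0.26, 0.62, 0.52 and 0.46 and mural markers at 0.48, 0.15, 0.94, 0.17 and 0.69. Glycolysis and hypoxia genes were near 0 at E11.5 (0.05), E13.5 (0.03) and E15.5 (-0.05) and higher at E12.5 (0.33) and E17.5 (0.43), and at the preset correlation the list stayed called without E12.5 (0.0017) and without E17.5 (0.0397), but over all stages it did not hold with an estimated correlation (0.509) or by fry (0.32).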
